A study of Mus musculus with 6 samples.

How the data were processed

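RNA from whole mouse kidneys (metanephros, the embryonic kidney) at embryonic day 14.5 was measured on 6 one-colour Affymetrix MG_U74Av2 arrays, 4 of wild-type and 2 of Wnt4 mutant kidneys. Per the labels, each wild-type sample pooled 2 kidneys, and each mutant sample pooled 8 to 10 kidneys from 4 to 5 embryos carrying the Wnt4tm1Amc allele. The number of embryos behind a wild-type pool is not given in the sources used here. The SDs and p-values may therefore rest on spread between single embryos in the wild type and between larger pools in the mutant. The strain is labelled CD-1 for the wild type and 129 for the mutant, while the protocol text of all 6 samples speaks of CD-1 matings. Strain label, pool size and genotype therefore could not be separated. Per the labels, total RNA was amplified in 1 round and labelled with biotin.

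The deposited values are linear probe set signals (intensity), made by the authors with GCOS, the Affymetrix array software, per the submitters' processing notes. Its version, algorithm settings and any background step are not given in the sources used here. In each deposited column the mean signal without the lowest and highest 2% of values lay between 500.27 and 500.29, so each array had already been scaled to a common level of about 500. Detection calls were not used here, and the number of arrays limits the precision. Signals ran from 0.21 to 36134 over the 6 arrays. No 2 arrays shared more than 0.0403% of their values, so none was counted as a copy of another.

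Gene names came from the platform annotation and were updated by gene identifier to the mouse RefSeq table of assembly GRCm38.p6, which was used for names and for which genes lie near each other. Of 12422 probe sets, 10833 had 1 gene symbol, 396 had several and 1193 were unnamed here. Of those with 1 symbol, 10817 matched the RefSeq table and 16 kept the older name. No gene was named from a probe set with several symbols. The 66 Affymetrix control probe sets were set aside.

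Probe sets were kept when their signal exceeded the 40th percentile of its own array on at least 2 arrays, which kept 7981 and dropped 4441. The kept probe sets covered 6082 genes, 998 of them through several probe sets. A gene was represented by its probe set with the highest mean log2 value, and its other probe sets could differ. Beside those given with the results, further probe sets had the opposite sign for Penk (-0.21), Tubb3 (-0.17), Tfcp2l1 (0.10) and Ncam1 (0.04), which passed at neither probe set. Further probe sets went the same way without passing for C1qb (0.33, adjusted p = 0.658), Bcl2l11 (0.47, 0.608), Plagl1 (0.53, 0.0604), Tnnt1 (0.69, 0.172), Peg3 (1.84, 0.366; 0.88, 0.0784), Capn6 (0.52, 0.0533), P4ha2 (1.02, 0.0512) and Emcn (-0.38, 0.576). Values were analysed as log2(signal + 16) with no further normalization. Differences are mutant minus wild type on that scale, which understates the change of genes with low signals. The test was limma (version 3.58.1 under R 4.3.3; lmFit, then eBayes with a variance trend), with no covariate and with Benjamini-Hochberg adjustment over all kept probe sets, at a threshold of 0.05. Means are given with their SD over 4 wild-type and 2 mutant arrays. With 4 arrays against 2 there are 15 ways to split the samples, so no permutation share below 0.0667 can be reached.

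The 20 gene lists were fixed before the data were examined: renal vesicle and early nephron, podocyte and glomerulus, proximal tubule, loop of Henle and distal tubule, Notch pathway, epithelial junction and polarity, cap mesenchyme nephron progenitor, ureteric bud and collecting duct, cortical and medullary stroma, fibroblast matrix and smooth muscle, endothelium, erythroid, macrophage and leukocyte, adrenal cortex and gonadal steroidogenic, adrenal medulla with neural and glial, cell proliferation, p53 response and apoptosis, immediate early and tissue handling, hypoxia and glycolysis, and Wnt ligands with receptors and targets. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 20 lists. With an estimated correlation camera also takes its degrees of freedom from the 6 arrays, and with the preset one from the number of genes. A list's counts of genes past the threshold are given over all probe sets and adjusted over the list alone. Another 4 lists (skeletal muscle, cartilage, imprinted genes, and TGF-beta and BMP ligands and regulators) were chosen after the largest differences had been seen, adjusted among themselves, and are reported in the additional observations, the muscle list also beside the stromal lists.

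The genes named were set by a rule written before the data were examined. It took 14 fixed genes where measured, the 15 lower and 15 higher genes with the largest differences among those past the threshold whose mutant arrays lay outside the wild-type range, and from each list up to 4 past the threshold in its main direction, up to 2 in the other and up to 2 not past it with the highest level. The rule was applied to the 4 later lists in the same way. Some of these genes were left out of the text for length, and the alternatives and the check for outlying arrays covered all of them. Pdgfrb, Alas2 and Pou3f3 were named outside the rule, after their values had been seen. Of the fixed genes, Jag1, Ret and Nphs1 were not analysed here.

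The alternatives were quantile normalization, scaling to a common median, offsets of 1 and 64, no filter, a filter at the 60th percentile, no variance trend, array weights, a replicate block, leaving out each array in turn, a threshold of 2-fold, counts of genes, an estimated correlation, and the mean of a gene's probe sets. A fit without wild-type replicates 2 and 4, and tests of the renal vesicle and Wnt lists without Wnt4, were added after the data had been seen. The procedure was tested on simulated data made from the wild-type and mutant arrays, with 7915 probe sets kept. In these data, 200 probe sets were changed 2-fold or 4-fold, and a list of 20 other genes was shifted by 0.5. It recovered 88% of those changed 4-fold and 59% of those changed 2-fold. Of its 164 calls, 10 were false, where calls of the 20 shifted genes were not counted as false. The shifted list had a camera p of 8.61e-20, and a pair of unshifted lists had 0.396 and 0.961. Simulated values were drawn independently of each other, with the same SD in both groups. These p-values therefore say nothing about lists whose genes are correlated, or about groups of unequal spread. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.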

Results

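Gene expression was measured in whole embryonic mouse kidneys at E14.5 (days after mating), in 4 wild-type pools and 2 pools of kidneys mutant for Wnt4, a secreted signalling protein. Per the study's design text, Wnt4 is needed for induction of the renal vesicle, the first epithelial precursor of the nephron, and the comparison was made to find genes expressed in the renal vesicle and in the structures that derive from it. The median signal per array lay between 172.69 and 191.03. Correlations of log2 signals across probe sets were 0.939 to 0.969 among wild-type arrays, 0.969 between the mutant arrays and 0.918 to 0.934 between the groups. The first principal component held 44.3% of the variance and separated the groups. The next one (21.7%) set wild-type replicates 2 and 4 apart from the other arrays, on opposite sides, and the one after it (14.1%) set wild-type replicates 1 and 3 against replicates 2 and 4.

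The groups also differed in ways other than genotype. The wild type is labelled CD-1 and the mutant 129, and the mutant pools held more kidneys. BioB, a bacterial transcript added as a hybridization control, gave 1723 ± 121 (SD, n = 4) on wild-type and 940 ± 14.4 (SD, n = 2) on mutant arrays for its middle probe set, a difference of -0.86 (limma, adjusted p = 0.0432 over the 66 control probe sets). Its 5' and 3' probe sets had -0.86 and -0.85 (adjusted p = 0.0432 each). Controls of the same kind were lower too without passing: BioC (-0.31 and -0.39), BioDn (-0.38 and -0.20) and Cre (-0.16 and -0.14). Whether this bears on genes with low signals was not tested. The ratio of 3' to 5' signal for Gapdh was 0.826 and 0.830 in the mutant, within the wild-type range of 0.785 to 0.834, and that for beta-actin was 1.58 and 1.61 against 1.28 to 1.89.

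Wnt4 itself fell in the mutant. Its probe set read 829, 739, 946 and 699 in wild-type replicates 1 to 4 and 74.2 and 34.5 in the mutant replicates, a log2 difference of -3.59 ± 0.24 (SE; limma, adjusted p = 6.11e-05). Where this probe set lies relative to the altered part of the allele is not given in the sources used here. Both mutant arrays lay below all 4 wild-type arrays, as their labels say.

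In Wnt4 mutant kidneys the lists of renal vesicle and tubule genes were lower, and those of stromal and matrix genes higher, at a preset correlation between genes. With an estimated correlation these lists did not pass (adjusted p = 0.105 to 0.276), and the podocyte and nephron progenitor lists passed with neither. In the mutant, 488 probe sets were lower and 371 were higher at the threshold, 10.8% of the 7981 tested, representing 386 and 312 genes. Of these, 165 were at least 2-fold lower and 128 at least 2-fold higher, and 49 and 13 differed at least 4-fold. The mutant arrays lay outside the wild-type range for all 859 called probe sets, but a call itself selects for such separation. They did so for 37.4% of all tested, where interchangeable arrays would give 13.3% on average. Probe sets on the same arrays are correlated, and strain label and pool size differ with genotype. This share therefore cannot be assigned to genotype. Without wild-type replicates 2 and 4, a fit chosen after seeing the data, 496 were lower and 423 higher. The counts depended on the mutant arrays: without mutant replicate 1 they were 198 and 133, without mutant replicate 2 they were 188 and 114, and without wild-type replicate 1 the lower count was 320. Array weights raised them to 738 and 613.

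The largest falls included transporter and brush-border genes of the tubule. Pdzk1, a scaffold for transporters in the tubule brush border, had a log2 difference of -4.70 (684 ± 122 to 10.6 ± 0.62; adjusted p = 1.06e-05). Slc12a1, the sodium-potassium-chloride cotransporter of the loop of Henle, had -4.06, Keg1 had -3.78, the histamine-forming enzyme Hdc had -3.64, the protease Napsa had -3.63 and the Notch ligand Dll1 had -3.42. Slc34a1, the sodium-phosphate cotransporter of the proximal tubule, had -3.26, the brush-border protease Mep1a -3.21 and the microvillus protein Vil1 -2.96. Sult1d1, a sulfotransferase, had -2.75. H2-K2, from the class I histocompatibility genes, which differ in sequence between mouse strains, had -3.23. Ctse had -2.70 at its brightest probe set and -3.09 at another, while its last gave 0.46 (adjusted p = 0.222). Pla2g12a had -2.64 at its brightest probe set and -0.73 (adjusted p = 0.616) at its other. The mutant means of these genes, apart from Ctse and Pla2g12a, lay below the 40th percentile of signals on the mutant arrays (110.4 and 106.77). The sizes of such differences, and their order, therefore depend on the offset: Pdzk1 had -5.87 with an offset of 1 and -3.31 with 64, and Keg1 had -5.31 and -2.38.

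Among the largest rises were muscle and embryonic globin genes. Tnnc1, a troponin of slow and cardiac muscle, rose by 2.76 (51.0 ± 27.9 to 415 ± 47.3; adjusted p = 0.00241). Actc1, the cardiac form of sarcomeric actin, rose by 2.05 and Myl1, a myosin light chain, by 2.17. The embryonic globins Hbb-bh1, Hba-x and Hbb-y rose by 2.18, 1.78 and 1.66. Rises were also found for the protease inhibitor Serpina3n (2.12), the GATA cofactor Zfpm2 (2.05), the non-coding RNA Snhg6 (2.01), the nuclease and helicase Dna2 (1.99), Parm1 (1.86) and Ly6h (1.80). Cadps (2.18), Astn1 (1.92), Bhmt (1.83) and Mfap4 (1.82) passed the threshold with adjusted p of 0.0453, 0.0450, 0.0454 and 0.0258. The wild-type means of Tnnc1, Hbb-bh1, Cadps, Serpina3n, Zfpm2, Dna2, Astn1 and Bhmt lay below the 40th percentile of their arrays (101.12 to 109.54), and Tnnc1 had 3.12 and 2.08 with offsets of 1 and 64.

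Of 14 measured members of the renal vesicle and early nephron list, 9 fell, 0 rose and 5 did not pass, with 11 lower when adjusted over the list alone. The list median was -1.24 (camera adjusted p = 1.8e-09; adjusted p = 0.105 with an estimated correlation). Wnt4, the mutated gene, is itself a member. Of the other 13, tested without it after the data were seen, 8 fell and 5 did not pass, with a median of -1.09 (camera adjusted p = 5.03e-08; adjusted p = 0.137 with an estimated correlation). Besides Wnt4 and Dll1, the transcription factors Pax8 and Lhx1 fell by 2.23 (849 ± 101 to 176 ± 77.7; adjusted p = 4.96e-04) and 1.76 (adjusted p = 0.00377). The growth factor Fgf8 fell by 2.39 (adjusted p = 0.0194), the Wnt inhibitor Dkk1 by 1.92 and the cell cycle gene Ccnd1 by 0.81. Fgf8 had low signals (104 ± 27.2 to 6.64 ± 3.44) and exceeded the filter level only on wild-type replicates 2 and 4. With the filter, it was therefore not tested when either of these was left out. Npy had -0.81 (adjusted p = 0.101), and Sfrp2 differed by 0.05 (adjusted p = 0.775).

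**Figure D1:**
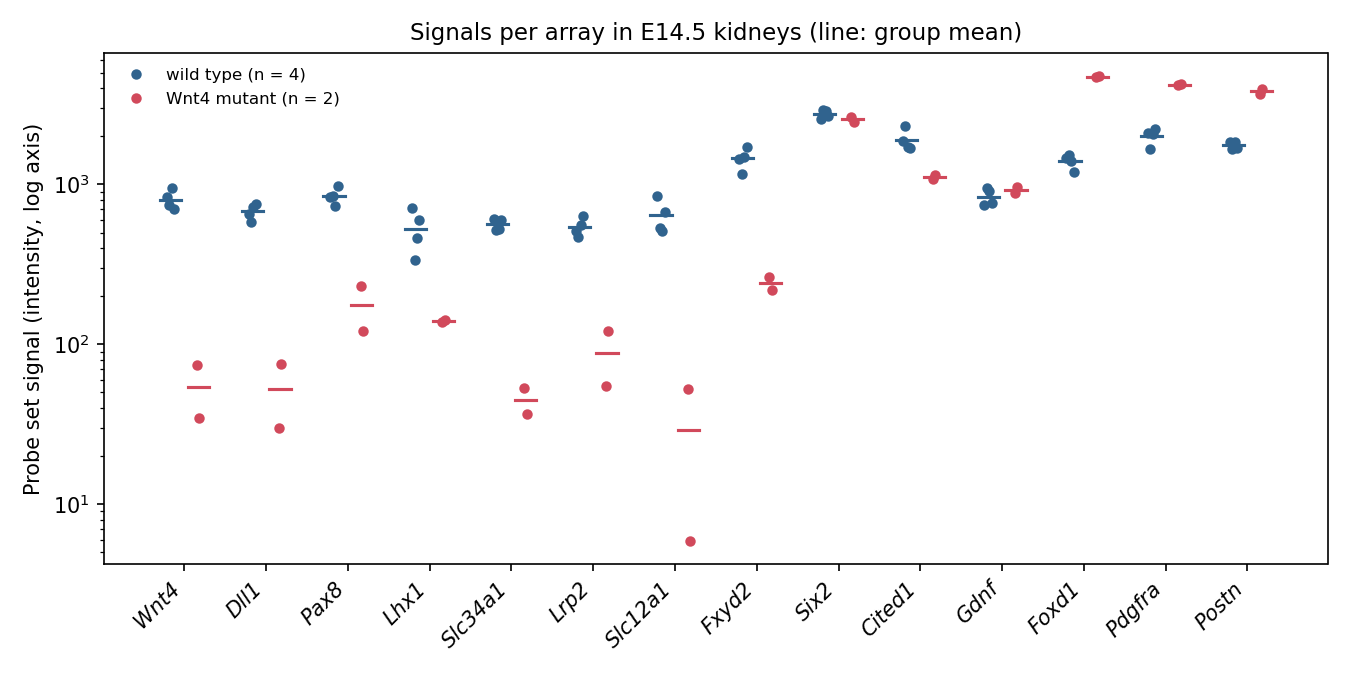
Probe set signal (intensity, log axis) of 14 genes on each of the 6 arrays, with points for arrays and lines for group means. The mutant arrays lie below all wild-type arrays for Wnt4, Dll1, Pax8, Lhx1, Slc34a1, Lrp2, Slc12a1, Fxyd2 and Cited1, above them for Foxd1, Pdgfra and Postn, and overlap them for Six2 and Gdnf, whose group means differ by -0.11 and 0.14 on the log2 scale.

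In the proximal tubule list, 7 of 16 measured genes fell, 0 rose and 9 did not pass (9 lower adjusted over the list alone), with a median of -1.14 (camera adjusted p = 4.57e-06; adjusted p = 0.149 with an estimated correlation). The median was -0.69 without mutant replicate 2, -0.75 with an offset of 64, and -2.49 over the 5 genes left by a filter at the 60th percentile. Lrp2, the endocytic receptor megalin, fell by 2.49 (544 ± 71.3 to 88.3 ± 47.0) and the organic anion transporter Slc22a6 by 2.12. Mme had 0.28 (adjusted p = 0.527) and Gatm -0.10 (adjusted p = 0.789). In the loop of Henle and distal tubule list, 4 of 9 fell, 0 rose and 5 did not pass, with 5 lower and 1 higher adjusted over the list alone. Its median was -0.64 (camera adjusted p = 6.77e-04, or 0.25 with an estimated correlation). The gene at the median was Pou3f3, which did not pass (-0.64, adjusted p = 0.633). Pou3f3 and Irx3 are also in the renal vesicle list and Calb1 in the ureteric bud list, so these lists are not separate evidence. Fxyd2, a subunit of the sodium pump, fell by 2.50 (1454 ± 233 to 242 ± 31.8), the calcium-binding protein Calb1 by 0.61 and the transcription factor Irx3 by 0.70. Pvalb had 0.49 (adjusted p = 0.0598) and Mecom -0.46 (adjusted p = 0.219).

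The podocyte and glomerulus list was mixed and did not pass as a set. Of 12 measured genes, 4 fell, 1 rose and 7 did not pass, with 6 lower and 1 higher adjusted over the list alone, and the median was -0.40 (camera adjusted p = 0.121). It passed without mutant replicate 1 (median -0.47, adjusted p = 0.0311) and without wild-type replicates 2 and 4 (-0.70, adjusted p = 0.0336), while the median was -0.049 with no filter and -0.093 with a filter at the 60th percentile (adjusted p = 0.181 and 0.451). Ptpro, a phosphatase of podocyte foot processes, fell by 2.76 (331 ± 65.2 to 42.9 ± 42.6), the matrix protein Npnt by 1.38, the tight junction gene Cldn5 by 0.93 and the angiogenic factor Vegfa by 0.87. The actin crosslinker Actn4 rose by 0.52. Wt1, a transcription factor of progenitors and podocytes, had -0.48 (adjusted p = 0.0823), and Tcf21 and Foxc2 had 0.13 and 0.22 (adjusted p = 0.368 and 0.226).

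The nephron progenitor markers did not pass as a set. In the cap mesenchyme list, 3 of 20 measured genes fell, 2 rose and 15 did not pass (5 lower and 2 higher adjusted over the list alone). Its median was 0.10 and its mean -0.09, and camera's direction was down (adjusted p = 0.733). The median turned negative with a replicate block (-0.077) and without wild-type replicate 4 or mutant replicate 2 (-0.02 each), was 0.038 without wild-type replicate 3, and was 0.17 with a filter at the 60th percentile. Six2, the transcription factor that maintains nephron progenitors, was 2762 ± 160 in the wild type and 2550 ± 131 in the mutant (-0.11, adjusted p = 0.479). Gdnf, the growth factor that draws out the ureteric bud, had 0.14 (adjusted p = 0.565). Uncx fell by 1.33 (2332 ± 166 to 919 ± 98.8), Meox2 by 0.94 and Cited1, a marker of the uninduced progenitors, by 0.76 (adjusted p = 0.00818). The cadherin Cdh11 rose by 0.69 and Capn6 by 0.45, and Ncam1 had -0.07 (adjusted p = 0.721).

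The ureteric bud and collecting duct list had 2 rises, 2 falls and 11 genes that did not pass among 15, with the same counts of 2 and 2 adjusted over the list alone (median 0.23, camera adjusted p = 0.183). This median was 0.37 without wild-type replicate 2, 0.35 without mutant replicate 2 (adjusted p = 0.0672), 0.14 without wild-type replicate 4 and 0.12 with no filter. The transcription factor Gata2 rose by 0.94 (693 ± 69.3 to 1343 ± 14.9) and the keratin Krt7 by 0.69, while Calb1 and Wfdc2 fell by 0.61 and 0.41. Gata3 had 0.47 (adjusted p = 0.117), Tfcp2l1 -0.12 (adjusted p = 0.426) and the bud tip ligand Wnt11 -0.05 (adjusted p = 0.937). Of 23 genes in the epithelial junction and polarity list, 4 rose, 4 fell and 15 did not pass, with 5 and 6 adjusted over the list alone (median -0.15, or -0.062 without mutant replicate 1, camera adjusted p = 0.366). The keratins Krt8 and Krt18 rose by 0.36 and 0.40 and the claudin Cldn3 by 0.43, and the membrane linker Ezr and the claudin Cldn6 fell by 0.72 and 0.53. Cdh16 had -0.23 (adjusted p = 0.143) and Tjp1 -0.02 (adjusted p = 0.906).

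In the cortical and medullary stroma list, 7 of 16 measured genes rose, 0 fell and 9 did not pass, with 10 higher and 1 lower adjusted over the list alone. The median was 0.56 (camera adjusted p = 1.93e-06; adjusted p = 0.105 with an estimated correlation). Foxd1, the transcription factor of cortical stroma, rose by 1.75 (1397 ± 141 to 4721 ± 40.3; adjusted p = 4.93e-05), as did the guidance factor Ntn1 (1.75), the matrix protein Smoc2 (1.43) and the growth factor receptor Pdgfra (1.06). A second Pdgfra probe set, near the low end of signals, had 0.35 (adjusted p = 0.779). The related receptor Pdgfrb, the 1 lower gene over the list alone, had -0.68 (adjusted p = 0.0713; 0.0172 over the list alone). Without wild-type replicate 2 it passed, with -0.81 (adjusted p = 0.0242). Markers of skeletal muscle, a list chosen after the data were seen, were higher too, with a median of 0.96 over 24 genes (camera adjusted p = 1.02e-06, or 0.0185 with an estimated correlation). These p-values were adjusted over the 4 later lists and are not comparable with those of the stroma list. Unadjusted, camera p with an estimated correlation was 0.00462 for muscle and 0.00902 for stroma. Without the 5 muscle genes already seen to be high, the other 19 had a median of 0.88 (camera p = 2.01e-04, or 0.0279 with an estimated correlation). Penk and Cdkn1c had 0.33 and 0.35 (adjusted p = 0.0937 and 0.0890). In the fibroblast matrix and smooth muscle list, 11 of 27 rose, 1 fell and 15 did not pass (12 higher and 1 lower adjusted over the list alone), with a median of 0.34 (camera adjusted p = 7.15e-05; adjusted p = 0.276 with an estimated correlation). The muscle markers were higher beside this list too. Without wild-type replicates 2 and 4 its median was 0.22 (adjusted p = 0.00120). Postn rose by 1.11 (1763 ± 90.1 to 3822 ± 167), Lum by 1.27, the collagen gene Col6a1 by 0.98 and Mfap2 by 0.64, all genes of extracellular matrix. Tagln, a smooth muscle gene, fell by 1.32, and the collagen genes Col1a1 and Col1a2 had 0.34 and 0.18 (adjusted p = 0.320 and 0.226).

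**Figure D2:**
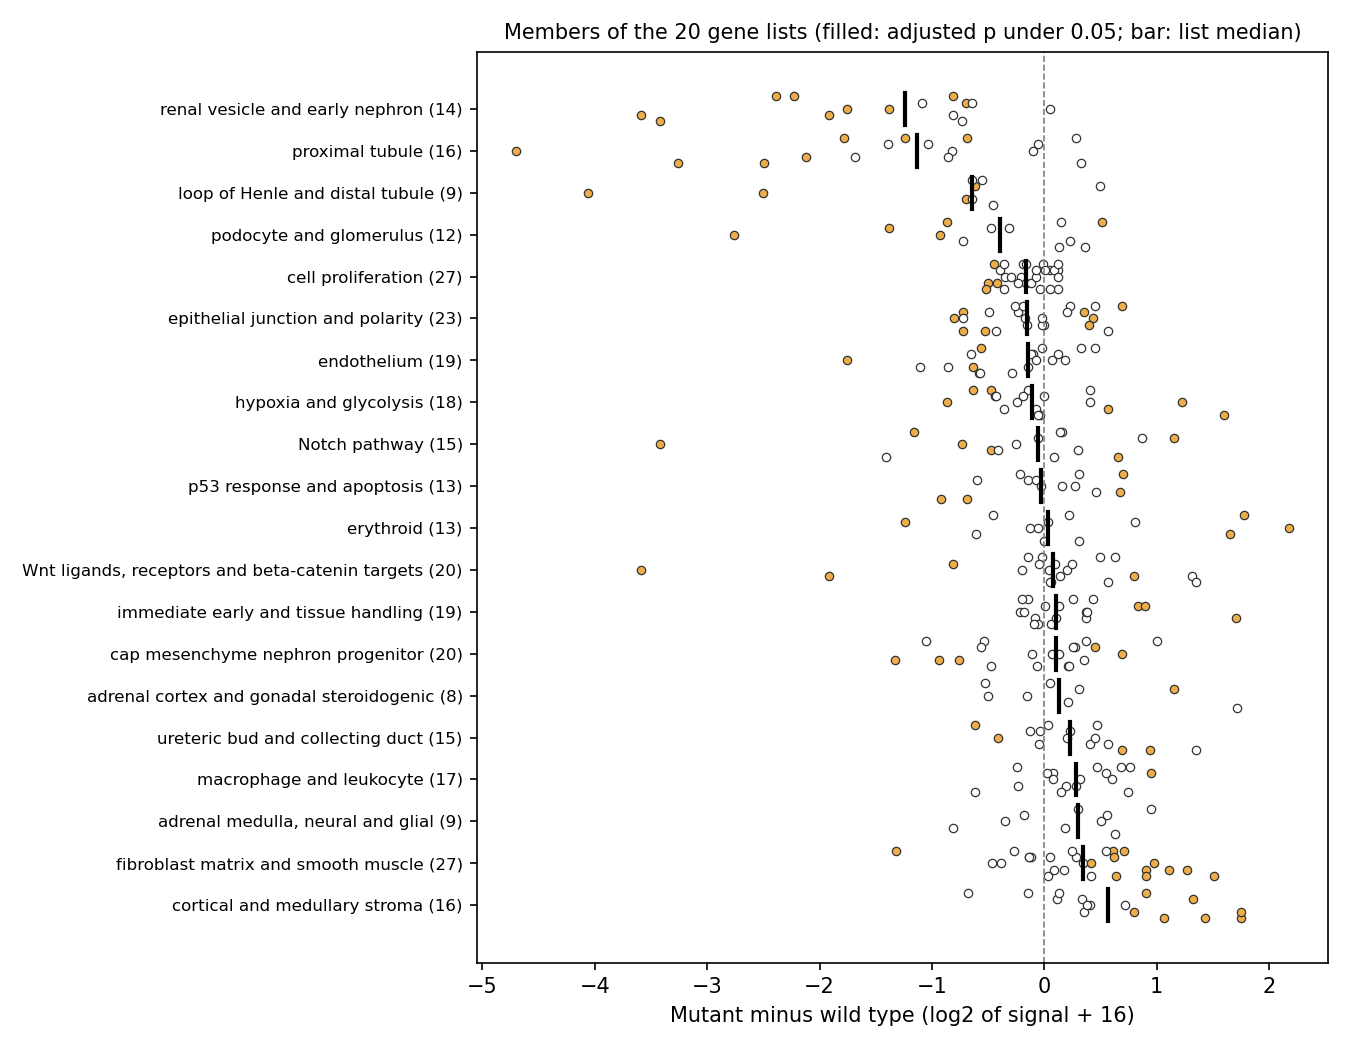
Log2 difference (mutant minus wild type) of each measured member of the 20 gene lists, with filled points for members past an adjusted p of 0.05, bars for list medians and the number measured in brackets. The medians run from -1.24 for renal vesicle and early nephron to 0.56 for cortical and medullary stroma.

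Notch and Wnt pathway genes moved in both directions. In the Notch list, 4 of 15 fell, 2 rose and 9 did not pass, with 5 and 3 adjusted over the list alone (median -0.05, camera adjusted p = 0.366). The median lay near 0 and changed sign with the setting: it was 0.084 with the mean of a gene's probe sets, 0.068 without wild-type replicate 2, 0.032 without wild-type replicates 2 and 4, 0.016 with a filter at the 60th percentile and -0.12 without mutant replicate 2. Beside Dll1, the target genes Hey1 and Hes1 fell by 1.16 and 0.47 and the receptor Notch1 by 0.73, while Notch3 rose by 0.66 and Dlk1 by 1.15. A second Notch1 probe set had -0.14 (adjusted p = 0.786). Adam10 and Rfng had 0.16 and 0.08 (adjusted p = 0.587 and 0.778). In the Wnt list, 3 of 20 fell (Wnt4, Dkk1 and Ccnd1), 1 rose (Sfrp1, by 0.80) and 16 did not pass, with 3 and 2 adjusted over the list alone. Its median was 0.07 and its mean -0.04 (camera up, adjusted p = 0.849), and over the alternatives the median ran from 0.025 without mutant replicate 1 to 0.14 without mutant replicate 2. Without Wnt4 the median was 0.093 and the mean 0.15 (adjusted p = 0.448). Beta-catenin, Ctnnb1, had 0.20 (adjusted p = 0.149).

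In the endothelium list, 4 of 19 fell, 0 rose and 15 did not pass, with 7 lower and 1 higher adjusted over the list alone. The median was -0.14 (camera adjusted p = 0.020; adjusted p = 0.171 with an estimated correlation), and the call was also lost with a filter at the 60th percentile (-0.087, adjusted p = 0.387). The median was -0.27 without mutant replicate 1, -0.28 with the mean of a gene's probe sets, and -0.21 with no filter or without wild-type replicates 2 and 4. The nitric oxide synthase Nos3 fell by 1.76, the TGF-beta co-receptor Eng by 0.58 and the adhesion gene Icam2 by 0.56. Emcn fell by 0.63 at its brightest probe set and had -0.10 (adjusted p = 0.609) at the next. Ramp2 and Efnb2 had -0.29 and 0.07 (adjusted p = 0.0769 and 0.726).

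In the erythroid list, 3 of 13 rose, 1 fell and 9 did not pass, with 3 and 2 adjusted over the list alone (median 0.03, camera adjusted p = 0.366). Over the alternatives this median ran from -0.0039 with a filter at the 60th percentile to 0.16 without wild-type replicate 1. The 3 that rose were the embryonic globins: Hbb-y went from 4119 ± 986 to 12750 ± 797 and Hba-x from 1306 ± 186 to 4486 ± 373. The adult globins Hba-a1 and Hbb-b2 were at 20969 ± 2374 and 10237 ± 2005 in the wild type and 20809 ± 291 and 10284 ± 77.1 in the mutant (adjusted p = 0.987 and 0.936). Car2, a carbonic anhydrase, fell by 1.24, and Alas2, which starts heme synthesis, had -0.46 (adjusted p = 0.0643; 0.0210 over the list alone). In the macrophage and leukocyte list, 1 of 17 rose and 16 did not pass, with 3 higher adjusted over the list alone (median 0.28, camera adjusted p = 0.0911). The list passed with a filter at the 60th percentile (0.60, adjusted p = 0.0227) and without a variance trend (0.28, adjusted p = 0.0403), while without wild-type replicate 2 its median was 0.13 (adjusted p = 0.0906). The complement gene C1qb rose by 0.95, and C1qc and Cd14 had 0.60 and 0.20 (adjusted p = 0.107 and 0.565).

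**Figure D3:**
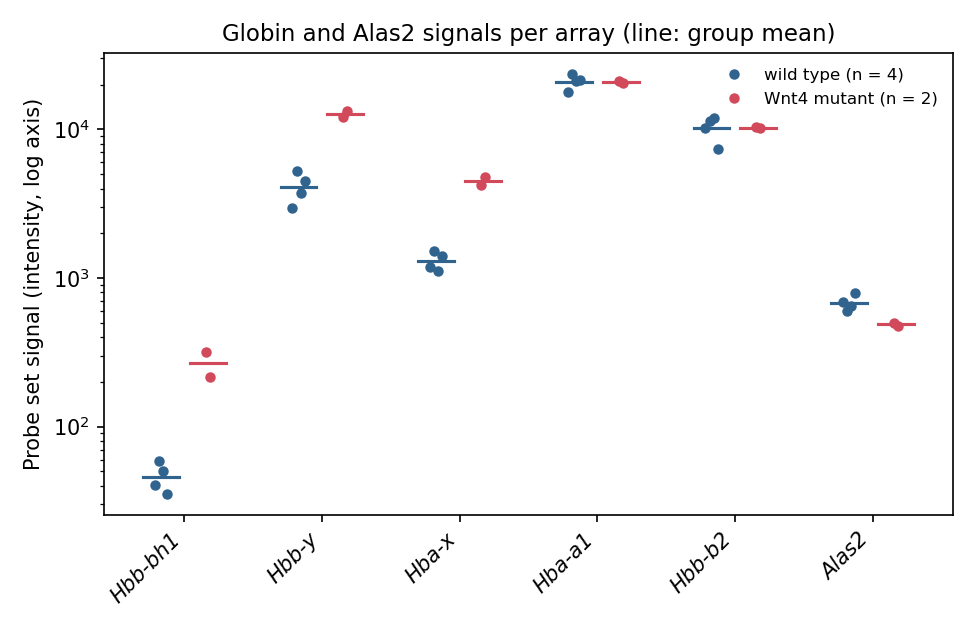
Probe set signal (intensity, log axis) of 5 globin genes and Alas2, the erythroid enzyme that starts heme synthesis, on each array, with points for arrays and lines for group means. Hbb-bh1, Hbb-y and Hba-x lie higher on both mutant arrays than on all 4 wild-type arrays, Alas2 lies lower on both than on all 4, and Hba-a1 and Hbb-b2 overlap between the groups.

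Markers of the neighbouring adrenal gland were also examined. In the adrenal cortex and gonadal steroidogenic list, 1 of 8 genes rose (Dlk1) and 7 did not pass, with 2 higher and 1 lower adjusted over the list alone (median 0.13, camera adjusted p = 0.366). The median was 0.043 without mutant replicate 1, 0.31 without mutant replicate 2 and 0.054 with no filter. Nr5a1, the steroidogenic transcription factor, had 0.31 (adjusted p = 0.128) and Fdx1 -0.15 (adjusted p = 0.643). In the adrenal medulla, neural and glial list, 0 of 9 passed, also adjusted over the list alone (median 0.30, limma camera adjusted p = 0.196), and the median was 0.50 without mutant replicate 2 and 0.13 with the mean of a gene's probe sets. Over all probe sets, 2118 had an unadjusted p under 0.05. The adrenaline-forming enzyme Pnmt and the neuronal tubulin Tubb3 had 0.63 and 0.19 (adjusted p = 0.0533 and 0.283).

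In the proliferation list, 4 of 27 fell, 0 rose and 23 did not pass, with 5 lower adjusted over the list alone, and the median was -0.16 (camera adjusted p = 0.010; adjusted p = 0.149 with an estimated correlation). Without mutant replicate 1 it was -0.10 (adjusted p = 0.0285). The DNA synthesis genes Rrm2 and Mcm7 fell by 0.52 and 0.50, and the mitotic regulators Cks2 and Cdk1 by 0.45 and 0.42. Pcna and Ccnb2 had -0.39 and -0.01 (adjusted p = 0.105 and 0.945). In the p53 and apoptosis list, 2 rose, 2 fell and 9 did not pass among 13, with the same 2 and 2 adjusted over the list alone (median -0.03 and camera up, adjusted p = 0.759), and the median ran from -0.079 with a replicate block to 0.16 with a filter at the 60th percentile. The apoptosis genes Bcl2l11 and Apaf1 rose by 0.67 and 0.70, and Gadd45a and Bid fell by 0.69 and 0.92. Bcl2 and Bcl2l1 had -0.15 and 0.16 (adjusted p = 0.439 and 0.701).

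In the immediate early and tissue handling list, 3 of 19 rose and 16 did not pass, also adjusted over the list alone (median 0.10, camera adjusted p = 0.192). The median was -0.059 with a filter at the 60th percentile and 0.026 without mutant replicate 2. The 3 that rose were the transcription factors Klf4 (1.71, 202 ± 42.2 to 686 ± 74.7) and Jun (0.90) and the antiproliferative gene Btg2 (0.84). Ier2 and Hsph1 had -0.06 and -0.08 (adjusted p = 0.729 and 0.815). In the hypoxia and glycolysis list, 3 rose, 3 fell and 12 did not pass among 18, with 3 and 5 adjusted over the list alone. Its median was -0.10 and its mean 0.01 (camera down, adjusted p = 0.366), and the median ran from -0.21 with a replicate block to -0.035 without mutant replicate 1. Pdk1, which restrains pyruvate oxidation, rose by 1.60, Bnip3 by 1.22 and the collagen hydroxylase P4ha2 by 0.57. The glycolytic genes Ldha and Aldoa fell by 0.63 and 0.47, as did Vegfa, and a second Aldoa probe set had -0.04 (adjusted p = 0.926). Tpi1 and Hk1 had -0.19 and -0.07 (adjusted p = 0.161 and 0.629).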

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

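The check for outlying arrays was set before the data were examined, and it compared the 4 wild-type arrays for 160 results, the named genes and 5 array measures. Chance marks about 1 in 20, and 13 were marked here, 8 of them for wild-type replicate 4. Each gene below had 1 wild-type array whose distance from the nearest other wild-type array took up most of the group's range on the log2 scale.

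On wild-type replicate 4, signals were lower than on the other wild-type arrays for Wt1 (852), Adam10 (838), Efnb2 (1554), Plagl1 (828), Tgfbi (651) and Sult1d1 (168), and higher for C1qc (479) and Tnnt1 (301). On wild-type replicate 1, Ptpro (428) and Serpina3n (86.1) were higher. On wild-type replicate 2, Icam2 was higher (548) and Bnip3 lower (159). On wild-type replicate 3, Nnat was lower (1098). No explanation was tested for these arrays.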

How the results depend on the processing

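The fit without wild-type replicates 2 and 4 and the lists without Wnt4 were chosen only after the data were seen, and the other alternatives were set beforehand. All 859 calls kept their sign in every setting that tested them, but their number changed: array weights gave 738 lower and 613 higher, a 2-fold threshold 165 and 128, and leaving out 1 array 188 to 553 lower and 114 to 448 higher. Of the fits with 1 array left out, those without a mutant array gave the smallest counts (198 lower and 133 higher without replicate 1, 188 and 114 without replicate 2), and there the lone mutant sample is assumed to vary like the wild type. The other settings gave counts within 1.5 times the main ones. The replicate numbers 1 and 2 occur in both groups, and same-numbered arrays had residual correlations of 0.003 and -0.02. The residuals of the 2 mutant arrays mirror each other, so unlike numbers gave the same sizes with the opposite sign (-0.003 and 0.02). These values give no sign that the numbers pair samples, and cannot exclude it. With a replicate block, 362 were lower and 341 higher, and 551 of these 703 were among the main calls. No detection limit was applied, so differences of genes with low signals are the least precise.

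With an estimated correlation, 0 of the 7 called lists passed: renal vesicle -1.24 (adjusted p = 0.105), proximal tubule -1.14 (0.149), loop of Henle -0.64 (0.25), stroma 0.56 (0.105), fibroblast matrix 0.34 (0.276), endothelium -0.14 (0.171) and proliferation -0.16 (0.149). The estimated correlation was -0.036 for endothelium and -0.015 for proliferation, below the preset 0.01, so these were not lost through correlation between their genes. It was 0.026 for stroma, 0.10 for renal vesicle, 0.11 for proximal tubule, 0.18 for fibroblast matrix and 0.24 for loop of Henle. This form of the test also rests on the few degrees of freedom of the 6 arrays. Endothelium was also lost with the 60th percentile filter (-0.087, adjusted p = 0.387), where macrophage and leukocyte passed (0.60; 0.28 without a variance trend). The podocyte list passed without wild-type replicates 2 and 4 (-0.70), and its median ranged from -0.53 to -0.28 when 1 array was left out. Camera's direction reversed, without a call, for the cap mesenchyme (median 0.17) and Wnt lists (0.053) with the 60th percentile filter, and for the Wnt list with the mean of probe sets (0.047) and without mutant replicate 1 (0.025, where leaving out any 1 array gave medians of 0.025 to 0.14). The cause was not tested. Pdgfrb and Alas2 were lower under all refits of single probe sets, and passed with array weights (-0.75 and -0.44). Pdgfrb also passed with quantile normalization (-0.72), without wild-type replicate 2 (-0.81) and without 2 and 4 (-0.92). Alas2 also passed with the 60th percentile filter (-0.46).

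Among the named genes, 2187 results under an alternative were as in the main analysis, 194 lost the threshold, 25 gained it and 38 reversed sign. Of those 38, 0 were past the threshold with either sign (limma; 2118 probe sets had an unadjusted p under 0.05). With wild-type replicates 2 and 4 left out they were Sfrp2 -0.039, Hba-a1 0.10, Hbb-b2 -0.10, Cd14 -0.021, Ccnb2 0.0067, Bcl2l1 -0.014 and Gnas 0.048. With the replicate block they were Gatm 0.063, Hba-a1 0.021, Hbb-b2 -0.073, Fdx1 0.040, Ccnb2 0.034 and Bcl2l1 -0.079. With quantile normalization they were Hba-a1 0.090, Ccnb2 0.010, Hk1 0.026 and Gnas 0.054. With array weights they were Hba-a1 0.024, Hbb-b2 -0.038 and Ccnb2 0.0028. With 1 array left out the ranges were Wnt11 -0.25 to 0.16, Rfng -0.089 to 0.26, Tjp1 -0.13 to 0.083, Ncam1 -0.17 to 0.029, Efnb2 -0.037 to 0.17, Hba-a1 -0.079 to 0.055, Hbb-b2 -0.12 to 0.11, Ccnb2 -0.049 to 0.036, Bcl2l1 -0.034 to 0.24, Hsph1 -0.28 to 0.11, Hk1 -0.14 to 0.00098 and Igf2 -0.037 to 0.096. The cause of these was not tested.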

Other observations

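The lists of skeletal muscle, cartilage, imprinted genes and TGF-beta factors were chosen only after the largest differences had been seen, and so were the share of second probe sets over all genes, the comparison of muscle genes with 6 lists of other cell types, and the tests of parts of the imprinted and muscle lists, apart from that of the 19 muscle genes. The other tests of an explanation were set before their results were seen, though the values of the 3 embryonic globins, the 5 muscle genes and a few of the probe set pairs were already known. Imprinted genes, which are expressed from 1 parental copy, were higher in the mutant: 5 of 18 measured rose, 0 fell and 13 did not pass (8 higher adjusted over the list alone), with a median of 0.38 (camera adjusted p = 2.05e-04; adjusted p = 0.0273 with an estimated correlation). The medians of 3 lists of other cell types were higher in the same comparison: stroma 0.56 (adjusted p = 0.105 with an estimated correlation), fibroblast matrix and smooth muscle 0.34 (adjusted p = 0.276 with an estimated correlation) and skeletal muscle 0.96 (adjusted p = 0.0185 with an estimated correlation). Cdkn1c is in both the imprinted and the stroma list. A probe set of Meg3 had been seen among the large rises before the list was chosen. The other 17 had a median of 0.37 (camera p = 1.91e-04; p = 0.0159 with an estimated correlation), and the 12 of them that did not pass singly had 0.23 (camera p = 0.0976). Plagl1, a zinc-finger gene, rose by 1.16, Dlk1 by 1.15, Nnat by 1.13 and Peg3 by 0.77, while Igf2 and Gnas had 0.01 and -0.04 (adjusted p = 0.950 and 0.817). Among TGF-beta and BMP ligands and regulators, 3 of 23 rose, 3 fell and 17 did not pass, with the same counts adjusted over the list alone (median 0.11, camera adjusted p = 0.768). The ligands moved apart: Tgfb3 rose by 1.61 (571 ± 92.5 to 1762 ± 56.3) and Tgfb2 by 1.24, and Tgfb1 fell by 2.32 (308 ± 94.0 to 47.2 ± 12.2). Tgfbi rose by 1.49, and Id2 and Id3 had 0.05 and -0.33 (adjusted p = 0.757 and 0.124). In the cartilage list, 1 of 9 fell (Pth1r, by 1.14), 0 rose and 8 did not pass, with 1 lower and 2 higher adjusted over the list alone (median 0.18, camera adjusted p = 0.768). Col9a1 and Col9a2 had 0.53 and 0.54 (adjusted p = 0.0966 and 0.0771).

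Skeletal muscle genes Actc1, Tnnc1, Myl1, Myod1 and Myog, the last pair chosen after their values were seen, were higher in the mutant, Actc1 going from 584 ± 165 to 2402 ± 134, while Eno3 of the muscle list had -0.24 (adjusted p = 0.224). Of 24 measured members of the muscle list, 9 rose, 0 fell and 15 did not pass (12 higher adjusted over the list alone), with a median of 0.96 (camera adjusted p = 1.02e-06; adjusted p = 0.0185 with an estimated correlation); 17 were above the filter level on at least 2 wild-type arrays and 0 were in a planned list. Skeletal muscle tissue in the mutant samples is a candidate explanation: the other 19 muscle genes had a median of 0.88 (camera p = 2.01e-04; p = 0.0279 with an estimated correlation), the 13 of them above the filter level on at least 2 wild-type arrays also had 0.88, and 37 measured with no filter had 0.54 (camera p = 1.47e-04; p = 0.0346). As the only change, a smaller share of epithelium that raised all other cell types alike is argued against for endothelium. Its median was -0.14, below that of the other 19 muscle genes by 1.02, more than both interquartile ranges (0.63 and 0.73). Of 6 lists of other non-epithelial cell types it was the only 1 to lie that far below. A separate loss of endothelium could hide such a rise and was not tested. A smaller share of epithelium that raised muscle and stroma alike stays open. The 5 genes exceeded the stroma list by 1.49 but had been picked as high, and the other 19 exceeded it by 0.32, inside its interquartile range of 0.85. Whether muscle tissue lay inside the kidney or was carried over in dissection, and whether strain or pool size plays a part, stays open.

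The embryonic globins Hbb-y, Hbb-bh1 and Hba-x were higher in the mutant. As the whole cause, more blood in the mutant kidneys is argued against. The other 10 erythroid genes had a median of -0.028, below the lowest embryonic globin (1.66) by more than their interquartile range of 0.55. Hba-a1 and Hbb-b2 are among these 10, and a rise could be compressed at their high signals. Alas2, with lower signals of 479 to 799 on the 6 arrays, had -0.46 (adjusted p = 0.0643). Mutant embryos at an earlier stage of the switch from embryonic to adult globins stay open: the log2 ratio of the embryonic globins to Hba-a1 was -3.05 ± 0.03 (SD, n = 2) in the mutant and -4.92 ± 0.09 (SD, n = 4) in the wild type, a difference of 1.87. This restates the rise of the embryonic globins and decides nothing, since Hba-a1 differed by -0.0039 and lay above the 99.7th percentile of signals on all 6 arrays, where a difference in its own level could be compressed. The labels give 1 stage for both groups, and the 129 and CD-1 strain labels, which differ with genotype, leave a strain difference in globin timing untested.

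Since strain label and genotype cannot be told apart here, sequence differences under the probes were weighed for the called probe sets. As the whole cause they are argued against: among 77 genes with a called probe set and a second kept one, both named without a suffix for shared probes (probe sequences were not used here), 75.3% of the second ones went the same way (58 of 77; exact 95% binomial interval 64.2% to 84.4%), though 15 of the 77 passed the threshold themselves in that direction, and over all 160 genes with any second probe set it was 79.4%. They may still account for single genes, or for genes whose probe sets overlap in sequence, since for genes called lower the second probe sets had a median of -0.13 against -0.66 for the called ones, while for genes called higher these were 0.52 and 0.73; Lrp6, chosen after its values were seen, had -2.88 at one probe set and 0.09 at another. An excess of calls in a strain interval around Wnt4 is also argued against: 23 of 233 probe sets within 20 Mb of it were called and 743 of 6995 elsewhere, an odds ratio of 0.92 (exact 95% interval 0.57 to 1.43). If the strains differed over the whole genome, as the labels allow, calls elsewhere would hold strain differences too. The odds ratio cannot decide that case. Differences in expression between strains away from the probes stay open, as do pool size and the lower signals of BioB and the other hybridization controls.

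The labels give the sex of the embryos as unknown. Xist, expressed from the inactive X chromosome, read 23.1, 36.0, 8.64 and 141 on wild-type replicates 1 to 4 and 117 and 84.3 on the mutant arrays. Eif2s3y, a gene of the Y chromosome, read 366, 253, 289 and 38.7 on the wild-type arrays and 160.2 and 126 on the mutant arrays. Uty, also on the Y chromosome, read 55.4, 45.8, 91.0 and 3.65 on the wild-type arrays and 85.3 and 59.0 on the mutant arrays, and Kdm5d read 6.75 to 17.4 over the 6 arrays. These genes were chosen after their values were seen, and no test was made of them.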
